A study of Mus musculus with 8 samples.

How the data were processed

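RNA was measured in 8 libraries of bone marrow LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of mouse marrow that holds stem cells and early progenitors. The mice were of the C57BL/6 strain and carried a model of chronic myeloid leukaemia (CML) that had been induced for 10 weeks. Per the labels, 4 libraries came from control (cre-negative) mice and 4 from mice with SIRT1 deleted (cre-positive), each described as a biological replicate. The labels number no replicates, so the numbers used here follow the order of deposit and pair nothing. Each column of the deposited table was matched to a sample by its title. The column of control 4 ends in another letter than the title of that sample, and it was matched because no other title shares its first part. The first digit of the titles differs between the genotypes, so whatever it stands for cannot be separated from genotype.

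Per the labels, libraries were made with version 4 of the SMARTer Ultra Low Input chemistry and Nextera XT. This chemistry does not mark strand and carries no molecular identifiers, so a gene and an overlapping antisense gene cannot be told apart and PCR copies are counted. The deposited values are whole-number counts of reads per gene, not normalised. The submitters' processing notes name bcl2fastq 2.18.0.12, Trim Galore 0.5.0, STAR 2.5.3, HTSeq 0.9.1 and DESeq2 1.20.0, with the mouse genome build GRCm38. The annotation release, the feature type and the strand setting of the counting are not given in the sources used here. The table held 48795 genes and 5 summary rows that name no gene. Those rows took 33.2 to 40.6% of the records of a library, most of them reads with more than one alignment (24.1 to 32.3%). They were kept out of library sizes and tests. Reads shared between near-identical copies are therefore missing, which makes counts of ribosomal protein genes, tropomyosin 3 copies and processed pseudogenes uncertain. Gene symbols came from the reference's name table, in which 48349 of the identifiers (99.1%) were found without their version and 41341 with it. Coordinates are those of the GENCODE annotation of GRCm38.

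Totals over genes ran from 18252562 to 34280925 counts per library. Genes were compared with the edgeR 4.0.16 quasi-likelihood F test (limma 3.58.1, R 4.3.3), two-sided, with TMM scaling, the filterByExpr filter, robust estimation and Benjamini-Hochberg adjustment over the 14178 genes tested. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute fold change over the square root of F. CPM values are the counts scaled by the TMM library sizes. Positive log2 fold changes mean higher in the Sirt1-deleted group. The biological coefficient of variation was 0.653.

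A total of 34 gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 34 lists. Camera with an estimated correlation and fry, which asks if the genes of a list move on balance one way, were run beside it. The score of a list in a library is the mean of the centred log2 CPM of its members, compared between groups by an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286. Lists share some members. Among them are Kit and Gata2 (stem cell and mast cell lists) and Egr1 (stem cell and immediate early lists). Ly6a is shared by the stem cell and interferon lists, and Nkg7 by the progenitor and lymphoid lists.

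The named genes follow a rule also fixed in advance. It takes 18 genes whatever their result (Sirt1 to Sirt7, Ppargc1a, Ppargc1b, Tfam, Trp53, Cdkn1a, Myc, Foxo1, Foxo3, Mki67, Abl1 and Bcr), up to 12 called genes per direction with groups that do not overlap and a mean of at least 5 CPM, predicted genes and pseudogenes left out, and up to 4 members of smallest p from each list that was called or concerns mitochondria. Other genes named were chosen after their values were seen, and are said to be so. Some results that the rule would name are not reported here.

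The procedure was tested on simulated data with 200 of 14178 genes changed between groups of the same sizes. The 200 were drawn from genes with a mean of at least 5 CPM, and the highest dispersions were capped. Recovery among genes of lower counts was therefore not tested. In the same data the oxidative phosphorylation list was shifted by -0.5, and calls of its members were not counted as false. EdgeR recovered 13% of the genes changed 2-fold and 70% of those changed 4-fold, with 6 false among 89 calls. DESeq2 recovered 41% and 86%, with 69 false among 203 calls, and limma-voom 12% and 67%, with 3 false among 83. The shifted list was recovered at -0.53. In data simulated with no change, edgeR called 0 genes and camera 1 list. Each simulated gene was drawn independently of the others. In the data the estimated correlation between members was 0.338 for oxidative phosphorylation genes and 0.583 for cytosolic ribosomal proteins. The simulation therefore cannot show how often camera calls lists of correlated genes.

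Alternatives fixed in advance were DESeq2 size factors, no TMM, no filter, a filter of 1 CPM in 4 libraries, mitochondrially encoded genes left out, each replicate left out, libraries whose titles start with 2 and 4 only, 1 surrogate variable (sva 3.50.0), estimation without robustness, DESeq2 1.42.0, limma-voom with quality weights, other thresholds, and the other list tests. Alternatives added after seeing the data left out immunoglobulin genes, removed each library's trend with transcript length and GC content, left out the 2 libraries with the fewest detected genes, or used the number of genes detected at 10000000 counts as a covariate. Length and GC content were those of the longest annotated transcript of each gene, and were known for 99.8% of the tested genes. All 8 libraries were counted as separate because the labels describe them as biological replicates. A chi-square test of counts cannot settle this here, since PCR copies spread even repeat libraries beyond counting noise. Its smallest value per degree of freedom, 63.9, was that of Sirt1-deleted 3 and 4.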

Results

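The data compared gene expression in LSK cells, the stem and progenitor fraction of mouse bone marrow, between CML mice with SIRT1 deleted and control CML mice. SIRT1 is an NAD-dependent deacetylase, and CML is driven by the BCR-ABL kinase. There were 4 libraries in each group, each described in the labels as a biological replicate, from cells sorted after 10 weeks of disease induction. Gene counts totalled from 18252562 to 28883834 per control library and from 24648721 to 34280925 per Sirt1-deleted library, and 15316 to 20342 genes had at least 1 count. Control 2 and Sirt1-deleted 1 had the fewest detected genes, 15316 and 16154. Spearman correlations had a median of 0.917 among controls, 0.938 among Sirt1-deleted libraries and 0.919 between the groups. The most alike pair was Sirt1-deleted 3 and 4 at 0.978, where no other pair exceeded 0.959. The first principal component held 32.7% of the variance and the second 19.4%. Immunoglobulin transcripts, which LSK cells are not known for, took 1.70 to 4.62% of the counts in controls and 0.867 to 12.96% in Sirt1-deleted libraries (exact permutation p = 0.171, adjusted p = 0.343 over 12 library measures).

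Sirt1 transcript level did not separate the genotypes. The gene (ENSMUSG00000020063.16, chromosome 10, 63319005 to 63381704, GRCm38) had 386, 498, 147 and 202 counts in controls 1 to 4 and 441, 391, 218 and 242 in Sirt1-deleted libraries 1 to 4. These are 13.1 ± 4.92 and 10.9 ± 4.24 CPM (SD, n = 4 each), a log2 fold change of -0.26 ± 0.39 (SE, edgeR adjusted p = 0.797). A count summed over the whole gene does not show whether exons are missing, so it neither checks nor contradicts the labels. The other sirtuins were not called either, with log2 fold changes from -0.26 (Sirt2) to 0.94 (Sirt6), the latter 0.51 without control 2, in which Sirt6 had 22 counts. Of the other genes fixed in advance, Trp53, which encodes p53, had 221 ± 27.3 CPM in controls and 278 ± 17.8 in Sirt1-deleted libraries (log2 fold change 0.33 ± 0.11, adjusted p = 0.204). The p53 target Cdkn1a had a log2 fold change of -0.40 (adjusted p = 0.547), Myc 0.20 (0.683), Foxo1 -0.25 (0.810), Foxo3 1.07 (0.574; 0.63 without control 2), Tfam -0.03 (0.969), Ppargc1b -0.21 (0.807), Mki67 0.36 (0.586), Abl1 0.19 (0.701) and Bcr -0.33 (0.661). None of the genes fixed in advance was called in any alternative, but the values moved. Over all alternatives Sirt1 ranged from -0.60 to -0.01, Trp53 from 0.21 to 0.40, Cdkn1a from -0.74 to -0.17, Myc from 0.02 to 0.41, Foxo3 from 0.50 to 1.53, Mki67 from 0.09 to 0.52 and Bcr from -0.76 to -0.16. The sign turned in at least 1 alternative for Foxo1 (-0.59 to 0.24), Tfam (-0.22 to 0.14), Ppargc1b (-0.48 to 0.055) and Abl1 (-0.04 to 0.36), and for Sirt3, Sirt4, Sirt5 and Sirt7. Ppargc1a, with 0 to 77 counts, was too low to test.

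Sirt1-deleted LSK cells had higher transcript levels of 7 genes and lower levels of 5, the latter including a gene of myeloid progenitors. Kit and 2 adhesion receptors had the smallest p, whereas Eng had the largest log2 fold change of the 7. Kit, the receptor for stem cell factor, rose 3.71-fold, from 37.0 ± 5.05 to 137 ± 20.99 CPM (SD, n = 4 each; log2 fold change 1.89 ± 0.17, edgeR adjusted p = 0.0145). Kit protein is also one of the markers the cells were sorted by. Adgrg1, an adhesion G protein-coupled receptor of stem and progenitor cells, rose from 529 ± 57.3 to 1475 ± 226 CPM (log2 fold change 1.48 ± 0.14, adjusted p = 0.0145). The related receptor Adgrl4 (log2 fold change 1.34), the transferrin receptor Tfr2 (1.79), the potassium channel Kcna3 (1.65), the TGF-beta co-receptor Eng (2.16) and the lipid carrier Apoe (1.79) also rose, with adjusted p from 0.0145 to 0.0487. Ms4a3, a gene of granulocyte-monocyte progenitors, fell from 661 ± 79.3 to 276 ± 42.5 CPM (log2 fold change -1.26 ± 0.14, adjusted p = 0.0298). The actin-severing protein gene Dstn (log2 fold change -1.45), the triglyceride synthesis enzyme gene Dgat2 (-2.19) and the tropomyosin-related Tpm3-rs7 (-1.79) fell as well. The remaining call was the processed pseudogene Gm9347 (-2.17), named after its value was seen. Counts of Tpm3-rs7 and Gm9347 are uncertain because each shares sequence with other loci.

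**Figure D1:**
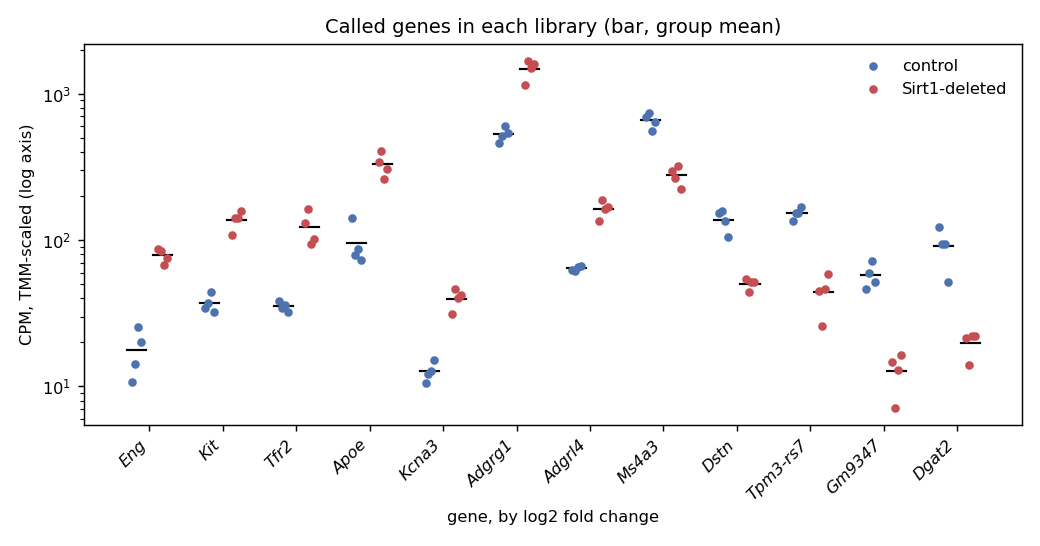
TMM-scaled CPM (log axis) of the 12 called genes in each of the 4 control and 4 Sirt1-deleted libraries, with a bar at each group mean. The groups do not overlap for any of the 12 genes. Kit, for example, has a mean of 37.0 CPM in controls and 137 CPM in Sirt1-deleted libraries.

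In all, 12 of the 14178 genes tested were called, 7 higher and 5 lower, and each kept its sign in all alternatives run. Since the groups do not overlap for these genes, leaving out libraries could hardly turn a sign, so the kept signs add little. At an unadjusted p under 0.05 there were 2290 genes, 1071 higher and 1219 lower, where evenly spread p-values would give 709. Other splits of the 8 libraries into groups of 4 gave 103 to 2144 such genes, so 709 is no measure of chance here. The groups did not overlap for 1855 genes (13.1%, where chance gives 2.86%). The count of calls depends on the libraries and the tool. It was 1, 0, 0 and 4 without controls 1 to 4, 451 without Sirt1-deleted 1, and 0 without Sirt1-deleted 2, 3 or 4. Without the 2 libraries with the fewest detected genes it was 311, 76 higher and 235 lower. DESeq2 called 1317 genes and limma-voom with quality weights 1139.

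Stem cell markers were higher in Sirt1-deleted libraries as a group. The 30 tested markers of haematopoietic stem cells had a median log2 fold change of 1.28, and 25 had positive values (camera adjusted p = 6.83e-08, adjusted p = 0.385 with an estimated correlation, fry adjusted p = 0.0203). Over all genes 1 member, Kit, was called. Adjusted over the list alone, 14 rose and 1 fell. Those that rose include Pdzk1ip1, at 10.1 ± 1.10 and 43.9 ± 16.7 CPM in controls and Sirt1-deleted libraries, the endothelial receptor Tie1, at 6.81 ± 4.38 and 51.2 ± 8.69 CPM, and Cd34, at 262 ± 33.9 and 471 ± 81.1 CPM. The member that fell was Ly6a, which encodes the sort marker Sca-1, at 405 ± 255 and 191 ± 49.2 CPM (edgeR adjusted p = 0.0477, adjusted over the list alone). Ly6a is also a member of the interferon response list, whose median was -0.83, and -0.23 without control 1. Ly6a was picked out after its value was seen.

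Markers of granulocyte-monocyte progenitors were lower. Their 25 members had a median log2 fold change of -0.48 and 17 were negative (camera adjusted p = 9.46e-05, adjusted p = 0.385 with an estimated correlation, fry adjusted p = 0.0409). Over all genes Ms4a3 was called, and adjusted over the list alone 13 fell. Among them, the Fc receptor gene Fcgr3 was at 126 ± 19.4 CPM in controls and 55.1 ± 14.6 in Sirt1-deleted libraries, the granule protease gene Ctsg at 2165 ± 380 and 1211 ± 204, and Plac8 at 1513 ± 240 and 1033 ± 100. The median was -0.28 with the length and GC trend of each library removed. Mature neutrophil markers had a median of -0.95 over 22 members (camera adjusted p = 3.38e-05, adjusted p = 0.487 with an estimated correlation, fry adjusted p = 0.210), and of -0.57 without control 1. None of these passed over all genes and 5 fell adjusted over the list alone. S100a9, an abundant neutrophil calcium-binding protein gene, was at 1014 ± 388 and 425 ± 119 CPM, Anxa1 at 242 ± 48.0 and 141 ± 7.55, and Retnlg at 77.2 ± 23.4 and 33.0 ± 8.46. The scores of the stem cell and progenitor lists separated all 4 controls from all 4 Sirt1-deleted libraries (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.108 over the 34 lists). The neutrophil scores overlapped (exact permutation p = 0.114).

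Nuclear genes of the respiratory chain and genes of both kinds of ribosome were lower together in Sirt1-deleted libraries. The 79 nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of -0.49 and 75 were negative (camera adjusted p = 9.91e-20, adjusted p = 0.385 with an estimated correlation, fry adjusted p = 0.0409). None was called over all genes, while 43 fell adjusted over the list alone. The cytochrome c oxidase subunit gene Cox5b was at 452 ± 7.44 CPM in controls and 296 ± 27.8 in Sirt1-deleted libraries (log2 fold change -0.61 ± 0.09, edgeR adjusted p = 0.0619). The complex I subunit genes Ndufs6, Ndufa5 and Ndufb11 had log2 fold changes of -0.72, -0.73 and -0.47. The 76 mitochondrial ribosome genes had a median of -0.40 (camera adjusted p = 7.94e-14, adjusted p = 0.385 with an estimated correlation). Of these, 29 fell adjusted over the list alone, among them Mrpl20 (-0.83) and Mrpl51 (-0.57). The 76 cytosolic ribosomal protein genes had a median of -0.54 with 75 negative (camera adjusted p = 4.03e-24, adjusted p = 0.470 with an estimated correlation). Here 63 fell adjusted over the list alone, such as Rpl34 (699 ± 21.1 and 466 ± 61.5 CPM). With the length and GC trend of each library removed, the medians were -0.18 for oxidative phosphorylation, -0.25 for the mitochondrial ribosome and -0.32 for cytosolic ribosomal proteins, all 3 still called by camera. Alignments set aside as not unique, which count for no gene, made up 32.0, 32.3, 30.1 and 30.6% of the total of the count table in controls 1 to 4 and 30.9, 28.8, 24.3 and 24.1% in Sirt1-deleted 1 to 4 (exact permutation p = 0.0857, adjusted p = 0.343 over 12 library measures). In the same Sirt1-deleted libraries the cytosolic ribosomal protein score was 0.10, -0.19, -0.54 and -0.49, against 0.14 to 0.41 in controls.

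**Figure D2:**
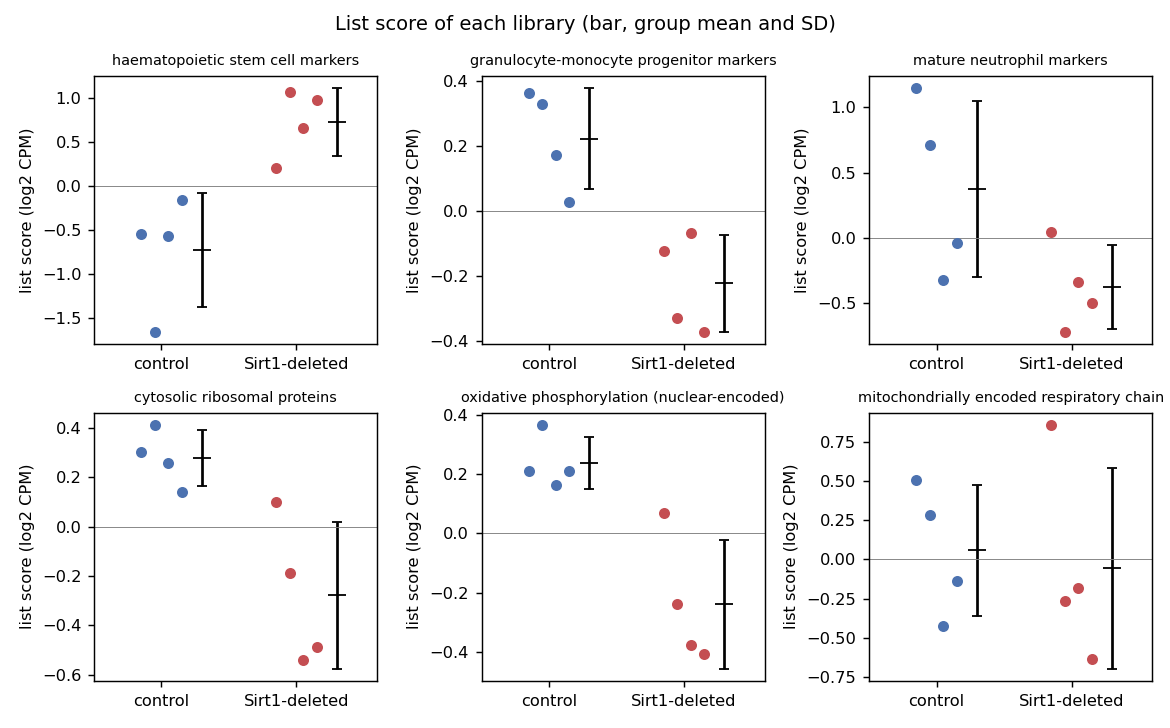
Score of 6 gene lists in each library, as the mean centred log2 CPM of the members. Points are libraries, and bars give the mean and SD of 4. The stem cell, progenitor, ribosomal protein and oxidative phosphorylation scores do not overlap between genotypes, whereas the neutrophil and mitochondrially encoded scores do.

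Genes of the respiratory chain encoded by the mitochondrial genome were not called as a list. Their 8 tested members had a median log2 fold change of -0.07 (camera adjusted p = 0.571). Values for mt-Nd1 were 1466 ± 363 CPM in controls and 1309 ± 832 in Sirt1-deleted libraries, and log2 fold changes were 0.15 for mt-Nd5, -0.28 for mt-Nd6 and -0.14 for mt-Nd2, each of which turned sign in at least 1 alternative. Without Sirt1-deleted 1 the median was -0.51 (adjusted p = 0.0204), so this list turns on 1 library, and with the length and GC trend removed it was 0.26 (adjusted p = 0.0716). The difference between the mitochondrial and the nuclear list was not tested. Lists of the TCA cycle (median -0.03, camera adjusted p = 0.571), fatty acid oxidation (0.08, 0.353), mitochondrial biogenesis and dynamics (-0.01, 0.655), autophagy and mitophagy (-0.05, 0.650) and NAD metabolism and sirtuins (0.10, 0.902) were not called. Over the alternatives these medians ranged from -0.16 to 0.03, 0.03 to 0.22, -0.08 to 0.11, -0.10 to 0.07 and -0.10 to 0.18 in the same order, so only that of fatty acid oxidation kept its sign. The scores of 2 of these lists nevertheless separated the genotypes and were higher in all Sirt1-deleted libraries (exact permutation p = 0.0286, adjusted p = 0.108 for each). Autophagy and mitophagy scored -0.38 to -0.03 in controls and 0.13 to 0.19 in Sirt1-deleted libraries, and mitochondrial biogenesis and dynamics -0.18 to -0.0003 and 0.03 to 0.10. Among their members, log2 fold changes were 1.07 for Cpt1a, the enzyme that admits fatty acids to mitochondria (adjusted p = 0.0950), -0.32 for Mdh2, -0.50 for Fis1, 0.95 for Atg13 and -1.51 for the NAD-consuming enzyme gene Cd38, none called.

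Of the other called lists, cholesterol and fatty acid synthesis was higher. Its 29 members had a median log2 fold change of 0.46 with 23 positive (camera adjusted p = 0.00256, adjusted p = 0.385 with an estimated correlation). Srebf2, the sterol-sensing transcription factor gene, was at 109 ± 22.0 CPM in controls and 205 ± 17.4 in Sirt1-deleted libraries, and was the 1 member that rose adjusted over the list alone. Immediate early genes had a median of 0.45 (camera adjusted p = 0.0308, adjusted p = 0.737 with an estimated correlation, fry adjusted p = 0.310), with Egr1 at 348 ± 74.9 and 904 ± 520 CPM, and 4 rose adjusted over the list alone. That call was lost without any of controls 1, 2 and 4 (adjusted p = 0.0594, 0.0590 and 0.152) and without Sirt1-deleted 1 or 2 (0.103 and 0.517). The median was 0.11 without Sirt1-deleted 2, 0.26 without control 2, 0.23 without the 2 libraries with the fewest detected genes (adjusted p = 0.130) and 0.08 in the titles starting with 2 and 4 (adjusted p = 0.693).

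Glycolysis had a median of -0.19 (camera adjusted p = 0.0308, adjusted p = 0.487 with an estimated correlation, fry adjusted p = 0.0831), with 8 of 23 members lower and 2 higher adjusted over the list alone. Gapdh was at 2405 ± 138 and 1544 ± 143 CPM and Aldoa at 1795 ± 180 and 1115 ± 70.4. The call was lost without control 1 or 2 (adjusted p = 0.113 and 0.105) or Sirt1-deleted 2 or 4 (0.0584 and 0.0619), with 1 surrogate variable (0.204), with detected genes as a covariate (0.146) and without the 2 libraries with the fewest detected genes (0.0839). The median was -0.30 without control 3, -0.31 without Sirt1-deleted 1 and -0.36 with the length and GC trend removed (adjusted p = 0.00214). MYC targets had a median of -0.26 (camera adjusted p = 0.00045, adjusted p = 0.487 with an estimated correlation, fry adjusted p = 0.103), with 7 lower, such as the nucleolar gene Ncl at 1375 ± 136 and 942 ± 166 CPM, and 2 higher adjusted over the list alone.

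Camera also called lower 3 lists, of mast cells, of T and NK cells and of interferon response, of which few members passed a test of their own. Mast cell and basophil markers had a median of -1.53 over 22 members (camera adjusted p = 3.38e-05, adjusted p = 0.487 with an estimated correlation, fry adjusted p = 0.239), and of -0.92 without control 1. No member fell, over all genes or adjusted over the list alone, and the 1 called was Kit, which rose. Fcer1a was at 126 ± 121 and 30.0 ± 14.1 CPM, with 306 CPM in control 1. T and NK lymphoid markers had a median of -0.91 (camera adjusted p = 0.000231, adjusted p = 0.550 with an estimated correlation, fry adjusted p = 0.310), with Ccl5 at 41.6 ± 16.0 and 8.70 ± 4.34 CPM, and 1 of 26 members fell adjusted over the list alone. That median was -0.60 without control 4, and -0.43 in the titles starting with 2 and 4, where the call was lost (adjusted p = 0.0588). Interferon response genes had a median of -0.83 (camera adjusted p = 0.00052, adjusted p = 0.619 with an estimated correlation, fry adjusted p = 0.366), with Isg15 at 334 ± 306 and 61.7 ± 23.8 CPM, and 6 of 42 members fell adjusted over the list alone. Without control 1 that median was -0.23 and the list was not called (adjusted p = 0.0866). The scores of all 3 lists overlapped between genotypes (exact permutation p = 0.0857 for mast cells and 0.343 for each of the others). For T and NK markers, Sirt1-deleted 3 and 4 (0.44 and 0.72) lay within the range of the controls (-0.62 to 1.45), and Sirt1-deleted 2 was the lowest at -2.46.

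**Figure D3:**
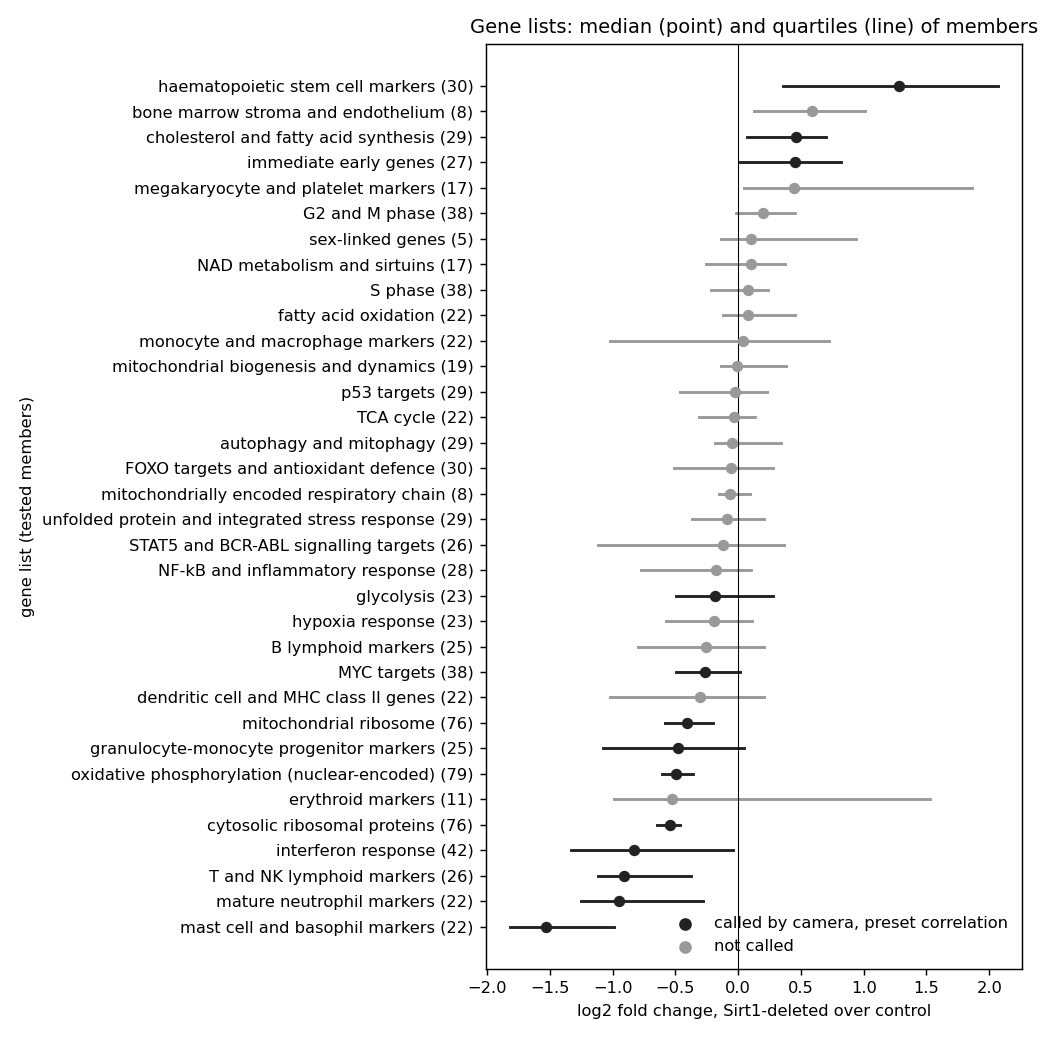
Median (point) and quartiles (line) of the members' log2 fold change, Sirt1-deleted over control, for the 34 gene lists, with the number of tested members in brackets. Dark marks are the 13 lists called by camera with the preset correlation, none of which is called with an estimated correlation. Stem cell markers have the highest median (1.28) and mast cell and basophil markers the lowest (-1.53).

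Camera called 13 lists in all, 3 higher and 10 lower, whereas 0 were called with an estimated correlation, 6 by directional fry and 28 by the mixed test of fry. The remaining lists were not called. Median log2 fold changes were 0.20 for G2 and M phase, 0.08 for S phase, -0.03 for p53 targets, -0.06 for FOXO targets and antioxidant defence, -0.12 for STAT5 and BCR-ABL signalling targets, -0.19 for hypoxia response, -0.18 for NF-kB and inflammatory response and -0.09 for unfolded protein and integrated stress response. Over the alternatives the median ranged from 0.07 to 0.27 for G2 and M phase, -0.04 to 0.15 for S phase, -0.09 to 0.05 for p53 targets, -0.17 to 0.04 for FOXO targets, -0.28 to 0.003 for STAT5 and BCR-ABL targets, -0.37 to -0.13 for hypoxia, -0.43 to 0.02 for NF-kB and -0.17 to 0.008 for unfolded protein response. NF-kB and inflammatory genes were called lower without control 2 (median -0.30, adjusted p = 0.0148) or Sirt1-deleted 2 (-0.39, 0.0240), in the titles starting with 2 and 4 (-0.43, 0.0450), with 1 surrogate variable (-0.23, 0.0208) and without the 2 libraries with the fewest detected genes (-0.27, 0.0182); the median was 0.02 without control 1. Hypoxia genes were called lower without control 4 (-0.30, 0.00879), in the titles starting with 2 and 4 (-0.37, 0.00935), with the length and GC trend removed (-0.37, 0.0132) and without the low-count filter (-0.17, 0.0415). The G2 and M phase list was called higher without the low-count filter (0.22, 0.0415), and STAT5 and BCR-ABL targets lower with the length and GC trend removed (-0.16, 0.0397). Camera and the median differed in sign for S phase, autophagy, mitochondrial biogenesis, monocyte and B lymphoid lists, none called.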

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

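The rule used in this part was fixed before the data were examined, and its extension from the called and fixed genes to all named genes was chosen after the first results were seen. In each group of 4, a library was picked out when its gap to the nearest other, over the group's range, exceeded Dixon's 95% critical value. Of 286 groups of values examined, 13 met this, where chance would give 14.3, about 1 in 20.

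Among the called genes, Dgat2 was at 13.9 CPM in Sirt1-deleted 2 against 21.6 to 22.2 in the others (gap ratio 0.925). For the score of NAD metabolism and sirtuins, control 2 was at -1.21 against 0.11 to 0.28 (0.888). Sirt1-deleted 2 also stood apart for Cd34, at 592 CPM against 419 to 444 (0.860), for Egr1, at 1679 against 595 to 729 (0.876), and for Gzma, at 0 against 1.198 to 1.43 CPM (0.839). Sirt1-deleted 1 stood apart for Cox5b, at 337 CPM against 279 to 288 (0.842), for Wfdc21, at 67.6 against 29.4 to 35.3 (0.846), and for Parp1, at 295 against 357 to 360 (0.947). In the control group, control 1 was at 306 CPM against 53.1 to 90.4 for Fcer1a (0.853). Control 3 was at 12.4 against 21.9 to 23.3 CPM for Cxcl10 (0.874) and at 7.14 against 22.3 to 23.7 for Cd38 (0.914). Control 4 was at 1583 against 2064 to 2098 CPM for Eno1 (0.934) and at 35.6 against 19.3 to 22.0 for Cpt2 (0.834).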

How the results depend on the processing

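Alternatives on immunoglobulin genes, length and GC content, poorly detected libraries and detected genes were chosen after seeing the data. All 12 called genes kept their sign in each alternative run, which leaving out libraries could hardly change because their groups do not overlap. The count of 12 (7 higher, 5 lower) stayed within 1.5 times under both other scalings, without the low-count filter, without mitochondrially encoded genes and with the length and GC trend removed, where 10 of the 12 were kept. Leaving out 1 library gave 0 to 451 genes in total, 0 to 79 higher and 0 to 372 lower, with 1556 to 2852 genes at an unadjusted p under 0.05. The highest counts came without Sirt1-deleted 1. Fewer samples give less power in the rest, but the cause of the 451 was not tested. The titles starting with 2 and 4 gave 1 gene (1 higher, 0 lower). With 1 surrogate variable 0 were called (0 higher, 0 lower), and 2361 genes had an unadjusted p under 0.05. With detected genes as a covariate 0 were called (0 higher, 0 lower), and 2195 genes had an unadjusted p under 0.05. Among the 12 genes the largest edgeR adjusted p was 0.0876 and 0.0783 in these settings, in that order. Over all alternatives the log2 fold change ranged from 1.62 to 2.02 for Kit and from -1.37 to -0.98 for Ms4a3. Estimation without robustness gave 7, of which 2 lower, and the CPM filter 9 lower. DESeq2 called 1317 (606 higher, 711 lower) and limma-voom with quality weights 1139 (376 and 763), and all 12 genes were among both. In simulated data 69 of 203 DESeq2 calls were false; the cause of the gap between tools was not tested. Without immunoglobulin genes there were 21 (12 and 9), without the 2 libraries with the fewest detected genes 311 (76 and 235), and at an adjusted p under 0.1 there were 136 (54 and 82), which follows from the threshold. Gene lists called numbered 13, 0 with an estimated correlation and 6 with fry. The oxidative phosphorylation median of -0.49 is the same with an estimated correlation and its call is lost, since its members are correlated (0.338). It ranged from -0.64 to -0.18 over 21 alternatives (adjusted p from 4.92e-25 to 0.385). The mitochondrially encoded list ranged from -0.51 to 0.10 with 1 library left out, and was called without Sirt1-deleted 1. Sirt1 was not called in any of 22 alternatives (adjusted p from 0.442 to 0.993). Depth was 18252562 counts or more per library. With 4 per group, edgeR recovered 13% of simulated 2-fold changes among genes with a mean of at least 5 CPM.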

Other observations

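Of the tests in this part, those on transcript length and GC content, on detected genes, on the position between stem and progenitor expression and on mature myeloid cells were chosen after the results were seen. The counts of other splits and the plasma cell and B cell tests were set out before their results were seen.

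Genes of several mature cell types were unevenly spread over the control libraries. Control 1 had the highest score of all 8 libraries for interferon response (1.34), mast cell and basophil markers (1.81), mature neutrophil markers (1.15) and erythroid markers (1.35). Megakaryocyte and platelet markers had a median log2 fold change of 0.45 over 17 members and were not called (camera adjusted p = 0.142), although their scores separated the genotypes, at -0.65 ± 0.94 in controls and 0.65 ± 0.20 in Sirt1-deleted libraries (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.108). Control 2 was the lowest at -1.96. That list was called higher without control 1 (median 0.83, adjusted p = 0.0168) and without the low-count filter (0.89, 0.0415), and its median was 0.25 without control 2 and 0.19 with the length and GC trend removed. Lists of bone marrow stroma and endothelium (median 0.59, 8 of 20 members tested, adjusted p = 0.215), monocytes and macrophages (0.04, 0.655), erythroid cells (-0.52, 0.658), B lymphoid cells (-0.26, 0.823), dendritic cells and MHC class II (-0.30, 0.486) and sex-linked genes (0.11, 0.571) were not called. All but the first of these medians changed sign when 1 library was left out, to -0.21 for monocytes without Sirt1-deleted 1, 1.18 for erythroid cells without control 1, 0.63 for B lymphoid and 0.03 for dendritic cells without control 4, and -0.17 for sex-linked genes without control 2. The sex-linked list joins Xist and Tsix with genes of the Y chromosome, so its median cannot show whether the sexes differed between the groups. The labels name no sex. The stroma and endothelium list was called higher without control 2 (median 0.69, adjusted p = 0.0329), Sirt1-deleted 1 (0.84, 0.0287) or Sirt1-deleted 2 (0.75, 0.0361), without the 2 libraries with the fewest detected genes (0.80, 0.00849) and without the low-count filter (1.38, 0.0332), and its median was 0.02 with 1 surrogate variable.

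The 8 libraries can be split into groups of 4 in 35 ways. For genes, 1 of the 35 splits, the real one, gave 12 calls, and the highest of the others gave 1. A share of 1 in 35 is the smallest this count can give, so it argues against chance without excluding it. The first digit of the titles differs between the same groups, so genotype and whatever it stands for cannot be told apart. For gene lists, 7 of the 35 splits gave 13 or more, the highest of the others 16, so chance cannot be excluded for the number of lists called with the preset correlation. Exchanging control 4 with Sirt1-deleted 1 gave 2144 genes at an unadjusted p under 0.05, close to the 2290 of the real split, but 0 calls.

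Ribosomal protein, mitochondrial ribosome and oxidative phosphorylation genes were lower together, with a median log2 fold change of -0.49 over the 231 members. Removing each library's trend with transcript length and GC content left -0.26, with all Sirt1-deleted scores still below all control scores. The length used was that of the longest annotated transcript, 4607 bases for Mrps35 for example, which may not be the one expressed. The removal can therefore be incomplete, and what remained cannot tell whether that trend is the whole cause, a part or none. With detected genes as a covariate the median was -0.41. This argues against library complexity as the whole cause and leaves open that it accounts for part. Within genotypes the pooled score had r = -0.59 (exact permutation p = 0.0938) and rho = -0.70 (p = 0.111) with the stem minus progenitor score, but r = 0.35 without control 2 and Sirt1-deleted 1, so the relation rests on those libraries, and a shift towards stem cells cannot be told apart from a change within cells. The lower share of alignments that were not unique in Sirt1-deleted 3 and 4 and an effect of genotype stay open and untested.

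Stem cell markers were higher and progenitor markers lower, their medians lying 1.76 apart on the log2 scale. With detected genes as a covariate they lay 1.51 apart. This argues against library complexity as the whole cause and leaves open that it accounts for part. Fewer mature myeloid cells in the Sirt1-deleted sorts may contribute and cannot be told apart from a shift among the LSK cells, since 3 of the 4 Sirt1-deleted libraries, and not all, had a neutrophil score below every control. A lineage gate with a myeloid antibody would remove mature neutrophils, though the antibodies are not given in the sources used here. A difference in how the Kit and Sca-1 gates were set and an effect of genotype stay open and untested.

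Immunoglobulin transcripts took 0.867% of the counts in Sirt1-deleted 2 and 12.8 and 12.96% in Sirt1-deleted 3 and 4. RNA of plasma cells is a candidate source. The score of 13 plasma cell markers other than immunoglobulins followed the share over the 8 libraries (rho = 0.881, exact permutation p = 0.00724, adjusted p = 0.0145 over 2 relations; r = 0.890, p = 0.00404), and r was 0.918 without the 2 libraries farthest from the median. Jchain was at 201 CPM in Sirt1-deleted 2 and 4414 in Sirt1-deleted 4, and Mzb1 at 37.5 and 242. Not every marker followed the share, since Fkbp11 was at 51.3 and 54.1, with its highest value, 119, in control 3. Of the 13 markers, 7 were at 10 CPM or more in the library with the lowest share, and 2 are also in the B lymphoid list. The 9 B cell markers gave rho = 0.119 (exact permutation p = 0.793) and r = 0.145 (p = 0.725), which leaves B cells open, and a lineage gate that includes B-lineage antibodies would remove both kinds of cell, though the antibodies are not given in the sources used here.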
